A study of Mus musculus with 18 samples.

How the data were processed

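The samples were laser-captured regions of mouse lung. Small adenomas driven by oncogenic KRAS alone (K), with loss of p53 (KP) or with loss of LKB1 (KL), and adjacent normal alveolar regions (NL) were captured, RNA was extracted with the PicoPure kit, and polyA RNA was made into QuantSeq 3' FWD libraries, which read the 3' end of transcripts. Per the labels, the authors' processing named FastQC, STAR 2.4.0j, RSEM and the builds GRCm38 and mm10, without stating their roles. The deposited file holds TPM per gene and library, transcript abundances that the authors divided by gene length and scaled to a common total within each library. Each column was checked to sum to 1000000 within 1, and no pair of the 136 pairs of libraries was identical. Because TPM keeps no read counts, the depth of every library is unknown, and no counting interval or limit of detection can be given. A 0 in it is therefore reported as listed at 0, not as absence. Division by gene length has no counterpart in 3' tag libraries, so levels of different genes within a library are not comparable as molecules.

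The labels list 18 samples, of which 17 have a column: 4 K, 5 KP, 4 KL and 4 NL. The K5 sample has no column, and 1 column, named as a KL5 library, matches no sample in the labels and was not used. The labels tie no region to an animal, so regions from 1 animal may stand in several groups. All p-values measure the spread between these libraries and may be too small for a statement about animals.

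Gene identifiers were matched to symbols and GRCm38 positions with GENCODE M21 (55144 of the 55471 identifiers). Genes at a TPM of 1 or more in at least 4 libraries were tested, 12239 in all, of which 7 have no symbol and 2558 were above 0 in every library. Values were transformed as log2(TPM + 1), which understates ratios of genes near 0. The 4 groups were fitted with limma 3.58.1 (lmFit, contrasts.fit, eBayes with a trend) in R 4.3.3, with the data.table package (version 1.17.8) for reading. The fit had 13 residual degrees of freedom, 1 fewer than planned for 18 libraries. There were 7 comparisons: the mean of the 3 adenoma groups against NL, each adenoma group against NL, and the 3 pairs of adenoma groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors of log2 changes are standard errors of the fit, and errors of TPM are SD between libraries.

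Gene lists, 41 in number, covered the interferon response, antigen presentation, markers of the cell types a captured region could hold, the pathways of KRAS, p53 and LKB1, metabolism, stress and growth. They were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 41 lists within a comparison. Camera compares a list with all other genes, so list changes are given as the mean log2 change of the list relative to that of the other genes. Camera with an estimated correlation and fry stand beside it. Member counts are given over all genes tested and adjusted over the list alone.

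The comparisons, the tests, the lists, the rule for naming genes and most other settings were fixed before the data were examined. The rule named Kras, Trp53 and Stk11 in every comparison. It then named up to 8 largest rises and 8 largest falls among called genes whose libraries did not overlap between the groups, without predicted gene models, or the 10 smallest p where fewer than 5 genes passed. It also named up to 4 members with the smallest p from each list described.

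Other settings chosen beforehand were pseudocounts of 0.1 and 5, no filter, a mean TPM of 5 or more, median-ratio scaling, quantile normalization, rescaling without mitochondrial, globin and surfactant genes, robust empirical Bayes, library quality weights, fits of only the groups compared, the number of genes above 0 as a covariate, the replicate number as a block, and each library left out in turn. Settings added after seeing the data were only genes above 0 in all 17 libraries, leaving out adenoma libraries with fewer than 10000 genes above 0, and leaving out, or fitting a term for, the 3 libraries whose column names carry the numbers 28 to 30 (K2, KL3 and KL4). The comparison was also tested on simulated data: with a log2 change of 6 added to 50 genes, 62% to 92% were recovered, depending on the comparison, and with a change of 2 at most 8%. False calls were 2 of 59 calls in KL against NL and 6 of 62 in KL against K. The simulation shuffled the residuals of each gene over the libraries and had no floor at 0. It therefore lacked the differences between libraries in genes above 0, and recovery in the real libraries may differ.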

Results

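Gene expression was measured in 17 laser-captured regions of mouse lung: 4 adenomas driven by oncogenic KRAS alone (K), 5 with p53 loss as well (KP), 4 with LKB1 loss as well (KL) and 4 adjacent normal alveolar regions (NL). LKB1 is the kinase encoded by Stk11, and p53 is encoded by Trp53. The values are TPM from 3' tag libraries, so the depth of each library is unknown. The number of genes above 0 was 13000 ± 1686 (SD, n = 4) in NL and 9574 ± 2363 (n = 13) in the adenomas, from 5610 in KP4 to 13708 in KP2. A mean of 10.9% of the tested genes was listed at 0 in NL libraries and 29.3% in adenoma libraries. Even genes that most cells express, such as Tbp and Hprt, were listed at 0 in several adenomas, so values of 0 are given per library and not as absence. Globin transcripts made up 6.16% ± 0.955 of TPM in NL and 0.405% ± 0.306 in the adenomas, and surfactant protein transcripts 1.43% ± 0.388 and 2.79% ± 0.83.

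**Figure D1:**
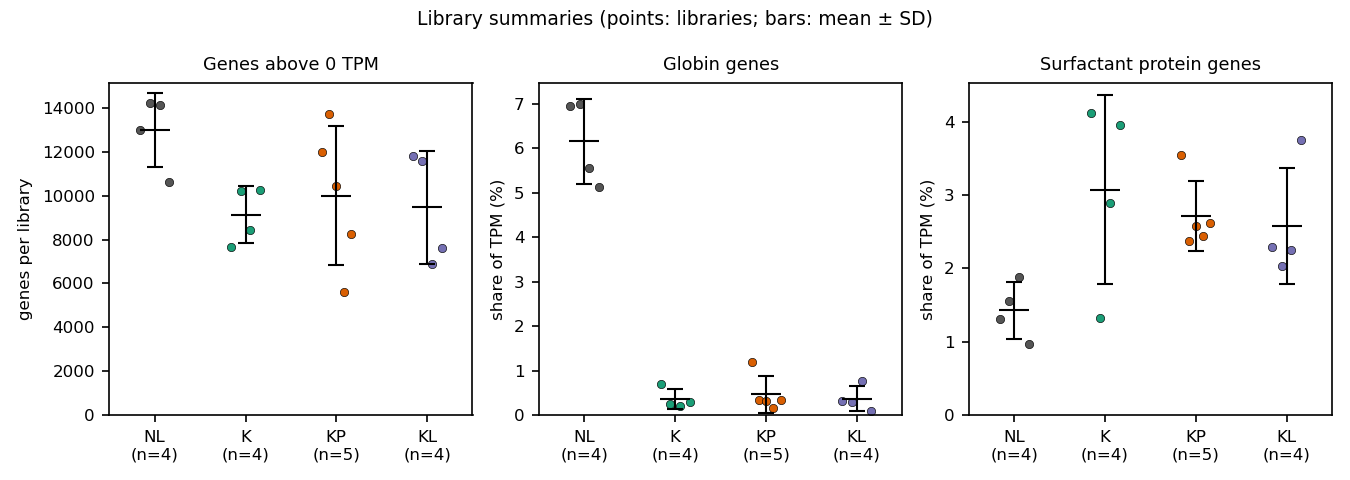
Number of genes above 0, percent of TPM from globin genes and percent of TPM from surfactant protein genes (vertical axes) in each library of the 4 groups (horizontal axes). Points are libraries and bars the group mean with SD; globin shares were 5.13% to 6.99% in NL and 0.09% to 1.2% in the adenomas.

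The 3 engineered genes were read first. Kras (6:145216699-145250239, GRCm38) averaged 200.4 ± 129.6 TPM (SD, n = 4) in NL, 117.9 ± 105.4 in K (n = 4), 293.5 ± 115.1 in KP (n = 5) and 219.8 ± 94.4 in KL (n = 4), with a log2 change of 0.53 ± 0.73 (SE) between adenomas and NL (adjusted p = 0.76, limma). Trp53 (11:69580359-69591873) was listed at 0 in 3 of 4 K, 2 of 5 KP and 2 of 4 KL libraries and at 1.84 to 20.04 TPM in NL. In K4 its log2(TPM + 1) was 4.765, above the 4.395 of NL1, the highest NL library. KP against K gave -0.52 ± 1.11 (limma adjusted p = 0.96). Stk11 (10:80115803-80130682) was at 15.01 to 279.22 TPM in K and at 0, 0.06, 6.45 and 19.75 TPM in the 4 KL libraries. Its log2 change of -3.92 ± 1.41 in KL against K did not pass over all genes (adjusted p = 0.918). Tags at the 3' end do not show whether an allele is mutated or deleted elsewhere in the gene.

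The comparison of all adenomas with adjacent normal lung asks what small KRAS-driven lesions express that the surrounding alveoli do not. Among the genes that rose were a pair of neighbouring imprinted noncoding RNAs of chromosome 12, Meg3 (ENSMUSG00000021268, 12:109541001-109571726) and Rian (ENSMUSG00000097451, 12:109603940-109661716). Meg3 averaged 36.1 ± 19 TPM in NL (SD, n = 4) and 1248 ± 735 in the adenomas (n = 13), a log2 change of 4.93 ± 0.59 (SE, adjusted p = 7.54e-05). Rian averaged 1.01 ± 0.52 and 136 ± 169 TPM, a change of 5.50 ± 0.81 (adjusted p = 0.000542). The metal-binding protein Mt2 (ENSMUSG00000031762, 8:94172664-94173568) rose by 5.27 ± 0.80 (adjusted p = 0.000549), and the mitochondrial ribosomal RNA mt-Rnr2 by 0.91 ± 0.19 (adjusted p = 0.00943). Clu, a secreted chaperone, averaged 83 ± 22.3 TPM in NL and 451 ± 197 in the adenomas, a change of 2.31 ± 0.53 (adjusted p = 0.0143). In each of these 5 genes every adenoma library lay above every NL library. Falls of genes whose libraries did not overlap were led by Hpgd, the prostaglandin-degrading enzyme (-6.70 ± 1.11, adjusted p = 0.00107), and the endothelial membrane protein Tmem100 (-6.54 ± 0.93, 0.000368). The methyltransferase Inmt (-6.45 ± 1.02, 0.000744), tau (Mapt, -6.25 ± 1.10, 0.00178) and Alas2 of erythroid heme synthesis (-6.22 ± 0.98, 0.000722) fell too. So did the dipeptidase Dpep1 (-5.89 ± 0.77, 0.000212), S100a8 of neutrophils (-5.57 ± 1.05, 0.00346) and Mfap4 of elastic fibres (-5.46 ± 1.15, 0.0085). Inmt went from 687 ± 121 TPM in NL to between 0.1 and 65.63 in the adenomas, and Tmem100 from 205 ± 44 to between 0 and 30.28.

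Of 12239 genes, 548 changed at an adjusted p under 0.05, 12 higher and 536 lower in the adenomas, and 2126 had an unadjusted p under 0.05. The labels tie no region to an animal, so these p-values measure only the spread between the libraries. The median change of all genes was -0.78. Quantile normalization moved it to 0.08 and gave 147 genes, 35 higher and 112 lower, so the excess of falls was smaller in that scaling. The call of Clu ended without NL1 (2.15, adjusted p = 0.0643) or NL2 (2.25, 0.0585) and with the number of genes above 0 as a covariate (0.0514, range over its alternatives 7.11e-05 to 0.0643). That covariate gave 108 genes. It also ended the calls of mt-Rnr2 (adjusted p = 0.18), Mapt (0.061), S100a8 (0.117) and Mfap4 (0.151), in each case the largest adjusted p over the alternatives of that gene. The number changed was 278 without NL1, 224 without NL2 and 294 without NL3.

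**Figure D2:**
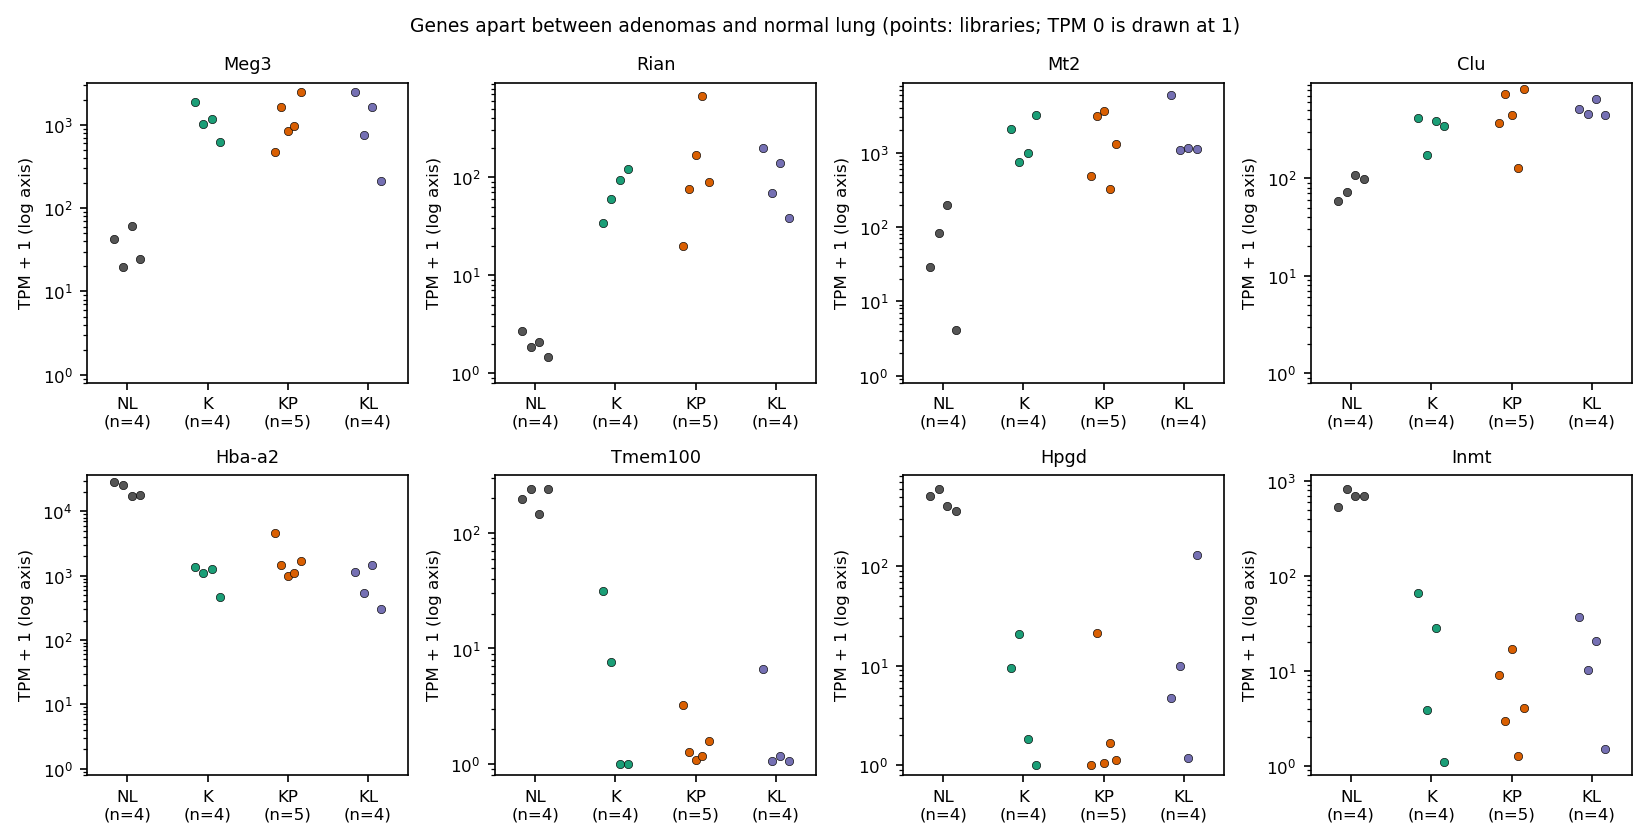
TPM + 1 on a log axis for Meg3, Rian, Mt2, Clu, Hba-a2, Tmem100, Hpgd and Inmt in each library of the 4 groups, with values of 0 drawn at 1. Each point is a library; Meg3 averaged 36.1 TPM in NL and 1248 TPM over the 13 adenoma libraries.

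Genes of blood, vessels and flat alveolar cells stood lower in the adenomas. All 5 measured red blood cell genes fell, with the alpha-globin Hba-a2 at 22440 ± 5714 TPM in NL and 1339 ± 1049 in the adenomas (-4.38 ± 0.43, adjusted p = 9.95e-06) and the beta-globin Hbb-bs at -3.81 ± 0.45 (7.54e-05). Of 23 endothelial genes, 7 fell and 0 rose (18 lower adjusted over the list alone), among them Clec14a (-4.60 ± 0.65, adjusted p = 0.000368) and Tmem100. Of 12 alveolar type 1 genes, 3 fell (10 adjusted over the list alone), with Igfbp2 at -4.60 ± 0.95 (adjusted p = 0.00754), a call that the covariate for genes above 0 ended (adjusted p = 0.116, range over its alternatives 0.000116 to 0.116). Relative to the other genes the mean log2 change of the list was -4.00 for red blood cells (camera adjusted p = 8.25e-12), -2.26 for endothelium (1.46e-10) and -1.90 for alveolar type 1 cells (1.46e-05). With an estimated correlation the adjusted p was 0.0141, 0.0141 and 0.0508. Smooth muscle and pericyte genes had 3 of 8 members lower and a relative mean of -0.97 (adjusted p = 0.0161, and 0.153 with an estimated correlation). Fibroblast genes had 2 of 12 lower, Inmt and Mfap4, and the list was not called (adjusted p = 0.256). Ciliated cell genes had 1 of 2 lower at a relative mean of -2.62 (adjusted p = 0.0239, 0.155 with an estimated correlation, and 0.0679 without NL4).

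Markers of alveolar type 2 cells, the surfactant-making cells, stood higher. Of 14, 2 rose (3 adjusted over the list alone): surfactant protein D, Sftpd, from 508 ± 113 to 1814 ± 609 TPM (1.76 ± 0.38, adjusted p = 0.00977) and surfactant protein B, Sftpb, from 1397 ± 283 to 3704 ± 1293 (1.36 ± 0.33, 0.0212). The relative mean of the list was 1.54 (camera adjusted p = 1.46e-10, and adjusted p = 0.0508 with an estimated correlation). The cell proliferation list had 0 of 29 members called in limma but 24 with a positive change, with Birc5 at 3.29 ± 1.24 (adjusted p = 0.153) and Ccnb1 at 2.03 ± 0.98 (0.288). Its relative mean was 1.74 (adjusted p = 9.88e-10, and 0.153 with an estimated correlation). The rise was not shared by all adenomas. The mean log2(TPM + 1) of the list was 1.608 to 2.157 in NL, and lower in K1 (1.372), K3 (1.438) and K4 (1.514). It was 5.569 in K2, 1.738 to 3.863 in KP and 2.054 to 3.485 in KL. Lung lineage transcription factors had 0 of 10 called and a relative mean of 1.40 (adjusted p = 0.00159, and 0.155 with an estimated correlation). In the keratin-high transitional epithelial list Clu alone of 13 passed, and the relative mean was 1.49 (adjusted p = 0.000112, and 0.155 with an estimated correlation). RAS-MAPK output genes had 0 of 18 called, among them Ereg at 2.34 ± 1.02 and Areg at 2.73 ± 1.23 and Ier3 at -2.96 ± 1.00, with a relative mean of 1.03 (adjusted p = 0.00137, and 0.155 with an estimated correlation). The covariate for genes above 0 ended the call of Sftpd (adjusted p = 0.167, range over its alternatives 0.000198 to 0.167). The call of Sftpb ended with it (adjusted p = 0.0908, range 0.000309 to 0.0908), with quantile normalization (0.0721), and without NL1 (1.35, 0.0667), NL2 (1.31, 0.0838) or NL4 (1.29, 0.0653).

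Interferon signalling is named in the title of the study. Type I interferon-stimulated genes stood lower in the adenomas: 33 of the 37 measured had a negative change, as did 77.1% of all genes tested. Of the 37, 5 fell and 0 rose (6 adjusted over the list alone). The antiviral gene Ifit3 was at 26.56 to 99.73 TPM in NL and at 0 to 30.93 in the adenomas (-4.32 ± 0.89, adjusted p = 0.00754), and its neighbour Ifit3b fell by 2.83 ± 0.57 (0.00623). The relative mean of the list was -1.02 ± 0.25 (SE, camera adjusted p = 0.000246), a call that did not hold with an estimated correlation (adjusted p = 0.155). Interferon-gamma-inducible genes had 1 of 18 lower (5 adjusted over the list alone) and a relative mean of -1.13 (adjusted p = 0.0023, and 0.233 with an estimated correlation). The lists of class I antigen processing (0 of 16 called, adjusted p = 0.144) and class II genes (H2-Ob alone of 10 lower, -3.29 ± 0.56, list adjusted p = 0.308) were not called. Nor were those of nucleic acid sensing (1 of 14 lower, adjusted p = 0.144) and of interferons with their receptors and kinases (0 of 9, 0.633). Immune checkpoints (1 of 9 lower, adjusted p = 0.372) and chemokines (1 of 12 lower, 0.981) were not called either. The checkpoint gene that fell was Cd274, which encodes PD-L1, at 10.69 to 33.43 TPM in NL (-3.54 ± 0.82, adjusted p = 0.0164). Its call ended without NL1 (-3.28, 0.0626) and with quantile normalization (adjusted p = 0.186, range over its alternatives 0.00103 to 0.186). That normalization also ended the call of Ifit3b (-1.20, adjusted p = 0.543, range over its alternatives 0.00283 to 0.543). The covariate for genes above 0 ended that of Ifit3 (-3.83, adjusted p = 0.1, range 0.000389 to 0.1).

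Immune cell markers were lower as well. T cell genes had 4 of 12 members lower (9 adjusted over the list alone), led by Cd247 of the T cell receptor complex (-3.75 ± 0.78, adjusted p = 0.00797, range over its alternatives 0.00257 to 0.147), and a relative mean of -1.85 (camera adjusted p = 2.18e-05, and adjusted p = 0.0508 with an estimated correlation). NK and cytotoxic genes had 2 of 3 lower and a relative mean of -3.47 (adjusted p = 0.00155, and 0.0355 with an estimated correlation). B and plasma cell genes had 3 of 15 lower, led by Ighd (-3.48 ± 0.55, adjusted p = 0.000744), and a relative mean of -0.98 (adjusted p = 0.0027, and 0.155 with an estimated correlation). Of 21 macrophage and monocyte genes only the scavenger receptor Marco passed (-4.96 ± 0.79, adjusted p = 0.00076), though 12 were lower adjusted over the list alone, and the relative mean was -1.19 (adjusted p = 0.00308, and 0.286 with an estimated correlation). Neutrophil genes had 4 of 9 lower and a relative mean of -1.31 (adjusted p = 0.0175, and 0.155 with an estimated correlation), and without NL4 the list was not called (-0.99, adjusted p = 0.104). Complement genes had 1 of 10 lower, Cfh (called in 10 of 31 alternatives, adjusted p up to 0.442), and a relative mean of -1.41 (adjusted p = 0.00443, and 0.155 with an estimated correlation). In all, 22 of 41 lists were called in this comparison, 4 with an estimated correlation and 22 with fry, which tests whether members move 1 way and does not compare them with other genes.

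**Figure D3:**
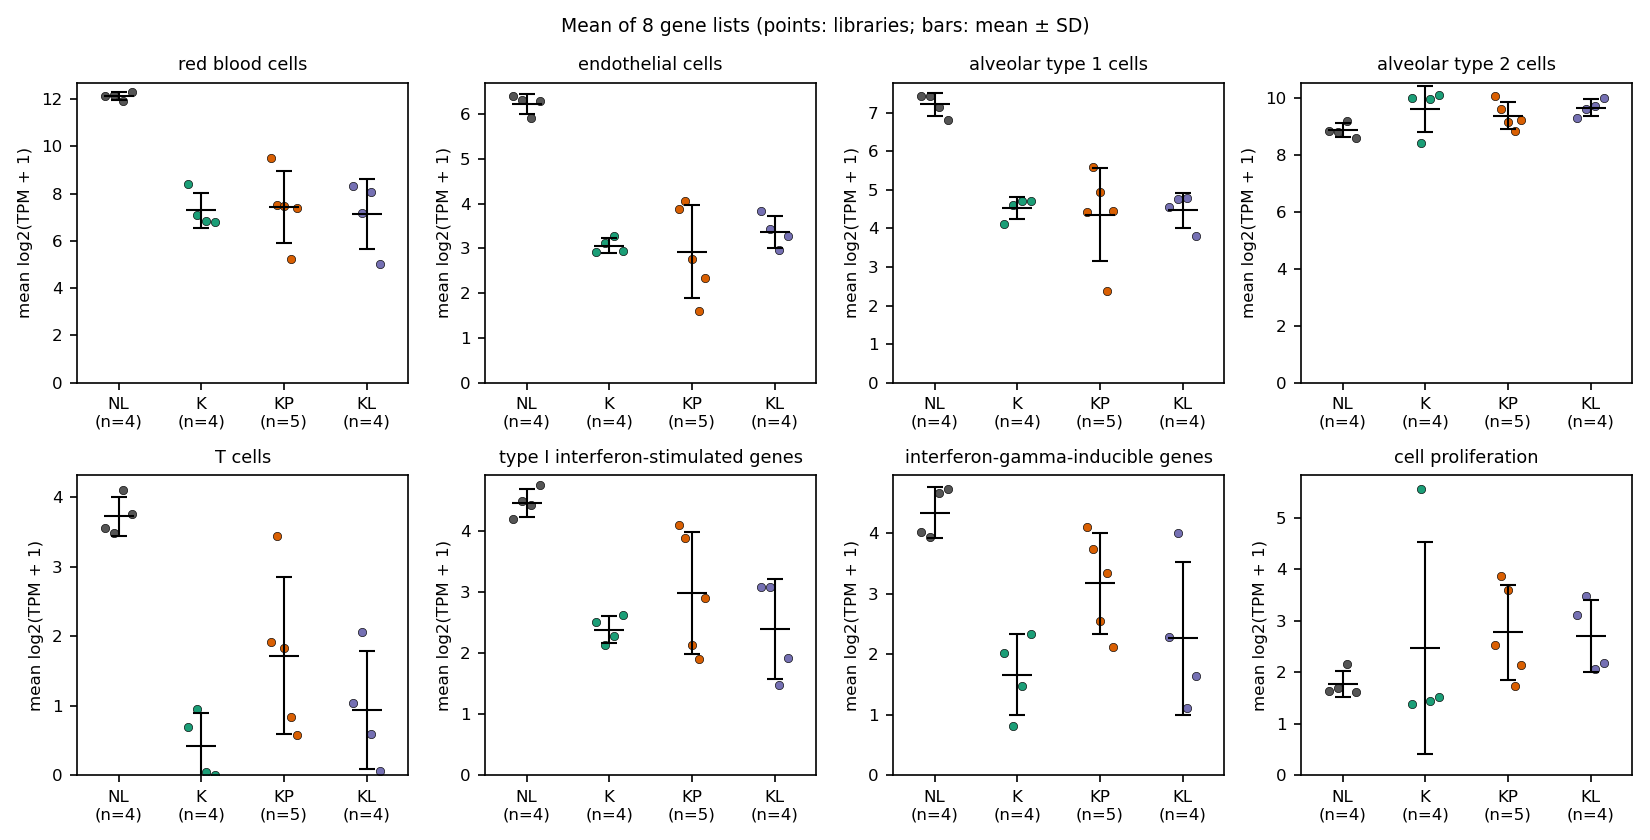
Mean log2(TPM + 1) of the measured members of 8 gene lists (vertical axes) in each library of the 4 groups, with the group mean and SD. Of the 37 type I interferon-stimulated genes, 33 had a negative change between adenomas and NL, and of the 29 proliferation genes 24 had a positive change. Of all genes tested, 77.1% had a negative change.

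The K group against NL asks what oncogenic KRAS alone is accompanied by. Metallothionein Mt2 (5.32 ± 0.98, adjusted p = 0.00738), Rian (5.14 ± 1.00, 0.00967) and Meg3 (5.03 ± 0.73, 0.00177) rose, each in all 4 K libraries (n = 4 against 4 NL). Falls included the junction protein Myzap (-7.33 ± 1.52, adjusted p = 0.0137), Mapt (-7.16 ± 1.36, 0.008), the lymphocyte protein Ms4a4b (-6.89 ± 1.18, 0.00451), S100a8 (-6.87 ± 1.29, 0.008) and Hpgd (-6.71 ± 1.37, 0.0123). Hba-a2 fell by 4.49 ± 0.54 (adjusted p = 0.00029) and Ifit3 by 5.47 ± 1.10 (0.0121), with Ifit3 at 0 to 0.48 TPM in K. The mitochondrial genes mt-Co3 (-9.37 ± 2.37, adjusted p = 0.041) and mt-Nd3 (-8.78 ± 2.00, 0.0238) passed. Among the 13 adenoma libraries mt-Co3 was under 1 TPM in 9 and between 73.15 and 5287.79 in the others, and mt-Nd3 was listed at 0 in 8.

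In this comparison 238 genes changed, 6 higher and 232 lower, and 1989 had an unadjusted p under 0.05. With quantile normalization 68 changed, 8 higher and 60 lower. Type I interferon-stimulated genes had 3 of 37 lower (8 adjusted over the list alone) and a relative mean of -1.22 (adjusted p = 0.000673, and 0.235 with an estimated correlation), and interferon-gamma-inducible genes 1 of 18 (9) and -1.82 (4.9e-05, and adjusted p = 0.207 with an estimated correlation). Among the 21 lists called, the 5 that held with an estimated correlation were endothelium (relative mean -2.31, adjusted p then 0.0238), red blood cells (-3.99, 0.0238), T cells (-2.44, 0.0407), NK and cytotoxic cells (-4.44, 0.0238) and ribosomal proteins (1.22, 0.0238). The ribosomal call ended with quantile normalization, which left a relative mean of 0.24 (adjusted p = 0.141). The proliferation list had a relative mean of 1.56 (adjusted p = 6.55e-06, and 0.242 with an estimated correlation) but was not called without K2 (0.58, adjusted p = 0.123). The count was 85 without K1, 124 without K2, 120 without K3, 133 without K4, 145 without NL1, 138 without NL2 and 158 without NL3. The covariate for genes above 0 ended the calls of Myzap (adjusted p = 0.121), Mapt (0.0969), S100a8 (0.1), Hpgd (0.0996), Ifit3 and Rian (0.0919 each), in each case the largest adjusted p over the alternatives of that gene. Those of Hpgd with a pseudocount of 0.1 (0.0568) and Mt2 without adenoma libraries under 10000 genes (0.0548) ended too. Leaving out single libraries ended the calls of mt-Co3 (each of the 8, adjusted p 0.0515 to 0.107) and mt-Nd3 (each but NL3, 0.0513 to 0.0615). It also ended those of Gbp9 (-6.55 ± 1.47, adjusted p = 0.0222; each but NL2, 0.0501 to 0.056), Mt1 (3.25 ± 0.80, 0.0345; each but K2 and NL3, 0.0574 to 0.104) and Sftpb (1.69 ± 0.41, 0.0319; each but K2 and NL3, 0.0665 to 0.102).

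With p53 loss added, KP against NL showed a rise of the secreted epithelial protein Dmkn (5.97 ± 1.15, adjusted p = 0.00945), at 119.64 to 815.71 TPM in the 5 KP libraries and 0.17 to 20.46 in the 4 NL libraries. Rian (5.79 ± 0.95, adjusted p = 0.00331), Meg3 (5.02 ± 0.69, 0.00104) and Mt2 (4.99 ± 0.93, 0.00748) rose here too. Falls included Myzap (-8.45 ± 1.44, adjusted p = 0.0038), Hpgd (-7.75 ± 1.30, 0.00331), Inmt (-7.17 ± 1.20, 0.00331), Tmem100 (-7.05 ± 1.09, 0.00208), Dpep1 (-6.54 ± 0.90, 0.00104), Mapt (-6.52 ± 1.29, 0.0112), the neuronal protein Nrgn (-6.52 ± 1.23, 0.00819) and Alas2 (-6.46 ± 1.14, 0.00541). Endothelial genes had 6 of 23 members lower (13 adjusted over the list alone) at a relative mean of -2.50 (adjusted p = 3.76e-11, and 0.0146 with an estimated correlation), and red blood cell genes 4 of 5 at -3.90 (3.76e-11, and 0.0198). Type I interferon-stimulated genes had 1 of 37 lower (2 adjusted over the list alone) at a relative mean of -0.67 (adjusted p = 0.0343, and 0.404 with an estimated correlation). Interferon-gamma-inducible genes had 0 of 18 called in limma and the list was not called (adjusted p = 0.417).

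In KP against NL, 182 genes changed, 8 higher and 174 lower, and 1585 had an unadjusted p under 0.05. With quantile normalization 53 changed, 13 higher and 40 lower. Of 17 lists called, 2 held with an estimated correlation. The interferon-stimulated list was not called without KP2 (-0.69, adjusted p = 0.0574), KP3 (-0.42, 0.226) or NL4 (-0.45, 0.209). The count was 73 without KP3, 82 without KP4, 61 without KP5, 86 without NL1, 84 without NL2 and 116 without NL3. Among the genes named above, the call ended in 3 of 24 alternatives for Mapt (adjusted p up to 0.0791), 2 of 24 for Nrgn (0.0663), 2 of 25 for Mt2 (0.065) and 1 of 25 for Dmkn (0.0932). The calls of S100a14 (5.43 ± 1.36, adjusted p = 0.0442; each left out but KP1 and NL1, 0.0657 to 0.144), Myh7 (4.45 ± 1.04, 0.0308; each but KP1, 0.0503 to 0.114) and Sftpd (1.89 ± 0.44, 0.0305; each but KP1, KP2 and KP4, 0.0533 to 0.0867) ended in most.

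With LKB1 loss added, KL against NL showed a rise of Dmkn (7.94 ± 1.22, adjusted p = 0.00245), at 377.87 to 2207.07 TPM in the 4 KL libraries. Rian (5.56 ± 1.00, adjusted p = 0.00742), Mt2 (5.50 ± 0.98, 0.00742), Ptprn (5.10 ± 1.06, 0.0174), a protein of secretory granules, and Meg3 (4.74 ± 0.73, 0.00245) also rose. Tmem100 (-6.88 ± 1.15, adjusted p = 0.00479), Nrgn (-6.88 ± 1.30, 0.00862), the adhesion adaptor Lims2 (-6.56 ± 1.25, 0.00894) and the actin regulator Evl (-6.34 ± 1.09, 0.0057) fell. Red blood cell genes had 4 of 5 members lower at a relative mean of -4.11 (adjusted p = 1.47e-10, and 0.044 with an estimated correlation), the only 1 of 19 called lists that held with it. Endothelial genes had 2 of 23 lower (10 adjusted over the list alone) at -1.97 (adjusted p = 2.03e-06, and 0.078 with an estimated correlation). Type I interferon-stimulated genes had 2 of 37 lower (4 adjusted over the list alone) at -1.19 (adjusted p = 0.000257, and 0.186 with an estimated correlation). RAS-MAPK output genes had 0 of 18 called in limma and a relative mean of 1.37 (adjusted p = 0.00021, and 0.135 with an estimated correlation).

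In KL against NL, 163 genes changed, 12 higher and 151 lower, and 1803 had an unadjusted p under 0.05. With quantile normalization 59 changed, 20 higher and 39 lower. The count was 94 without KL1, 94 without KL2, 47 without KL3, 60 without KL4 and 106 without NL2. It was 6 without both KL3 and KL4, a setting chosen after seeing the data that also leaves out K2. The call of Ptprn ended in 6 of 23 alternatives (adjusted p up to 0.151), among them without KL3 (4.83, 0.0589) or NL3 (4.73, 0.06), and those of Nrgn and Lims2 in 4 of 23 each (up to 0.158 and 0.155). Calls also ended in 2 of 24 alternatives for Rian and Mt2 (up to 0.12 each), 1 of 24 for Dmkn (0.101), and 1 of 23 for Tmem100 (0.13) and Evl (0.12). That of Inmt (-6.02 ± 1.26, 0.0178) ended in 5 of 24 (up to 0.238), among them without KL4 (-5.09, 0.0729). Those of Lst1 (-6.92 ± 1.64, 0.0345) and Abcg2 (-5.96 ± 1.42, 0.0355) ended with each of the 8 libraries left out (adjusted p 0.0588 to 0.104). Most left-out libraries ended the calls of Col15a1 (4.66, 0.0381; each but NL2, 0.0531 to 0.11), Rgs4 (4.61, 0.0406; each but NL3, 0.0718 to 0.112) and Celsr2 (4.25, 0.0487; each but KL1, 0.065 to 0.131).

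KP against K asks what p53 loss adds to oncogenic KRAS. Adenoma libraries of 1 genotype were about as alike as libraries of different groups. The median Spearman correlation of pairs was 0.5075 within K, 0.5305 within KP and 0.5165 within KL. It was 0.52 between groups and 0.6725 within NL. The polyubiquitin gene Ubb (ENSMUSG00000019505, 11:62551171-62553213) fell from 451.5 ± 96.6 TPM in K (SD, n = 4) to 13.1 ± 13.5 in KP (n = 5), a log2 change of -5.53 ± 0.83 (adjusted p = 0.0112), and was at 299 ± 210 TPM in NL. Ubb lies 7 Mb from Trp53 on chromosome 11. The actin regulator Evl (ENSMUSG00000021262, 12:108554720-108688516) was at 0, 0, 0.56 and 7.01 TPM in K and at 42.32 to 1060.82 in KP (6.42 ± 1.04, adjusted p = 0.0172), with 39.78 to 198.37 in NL. The p53 target Cdkn1a, the cell cycle inhibitor p21, averaged 304 ± 153 TPM in K, 30.2 ± 12.7 in KP and 82.7 ± 37.3 in NL. Its change of -3.18 ± 0.77 did not pass over all genes (adjusted p = 0.431), and it was the 1 of 25 p53 target genes that passed adjusted over the list alone. That list had 20 negative changes and was not called (adjusted p = 0.161), but was in 6 of 27 alternatives (range 0.00742 to 0.913), among them without K2 (-0.92, 0.00768). Interferon-gamma-inducible genes had 15 of 18 positive changes, with Cxcl9 at 4.01 ± 1.35 and Iigp1 at 2.59 ± 0.97 (each adjusted p = 0.932). The relative mean was 1.46 (adjusted p = 0.000165, and 0.771 with an estimated correlation). T cell genes had 10 of 12 positive, with Cd3d at 3.33 ± 1.29, and a relative mean of 1.25 (adjusted p = 0.0106, and 0.771 with an estimated correlation). Glycolysis and hypoxia genes had 16 of 21 negative, with Gpi1 at -2.57 ± 1.02, and a relative mean of -0.97 (adjusted p = 0.0266, and 0.885 with an estimated correlation). The type I interferon-stimulated list had a relative mean of 0.55 and was not called (adjusted p = 0.234).

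These were the only 2 genes called in KP against K (1 higher, 1 lower, 604 at an unadjusted p under 0.05), and 3 of 41 lists were called, 0 of them by fry. Limma called 0 genes without K1 and 4 without KP4 or KP5. Other genes with the smallest p did not pass, among them Trmt10a (5.34) and Tnfaip8 (5.18). The call of Ubb ended without K1 (-5.51, adjusted p = 0.0749) and in a fit of only these groups (0.477, range over its alternatives 0.00225 to 0.477). It ended also without adenoma libraries under 10000 genes (-4.88, 0.0879) and without the libraries numbered 28 to 30 (-5.43, 0.0501). That of Evl ended without K1 (6.11, 0.122), K2 (6.33, 0.0593) or K3 (6.11, 0.0888) and in that fit (0.622, range 0.00485 to 0.622). Evl was not called either with a pseudocount of 0.1 (8.42, 0.0658), with the replicate block (6.20, 0.0601), without adenoma libraries under 10000 genes (4.31, 0.139) or without those numbered 28 to 30 (6.33, 0.0501). The T cell list was not called without K3 (1.15, adjusted p = 0.0754), K4 (1.03, 0.118) or KP2 (1.02, 0.106). The glycolysis list was not called without K2 (-0.67, 0.165), K3 (-0.99, 0.0754), K4 (-1.05, 0.0542), KP2 (-1.01, 0.0622) or KP4 (-0.47, 0.394). The interferon-stimulated list was called without KP3 (0.80, adjusted p = 0.026).

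**Figure D4:**
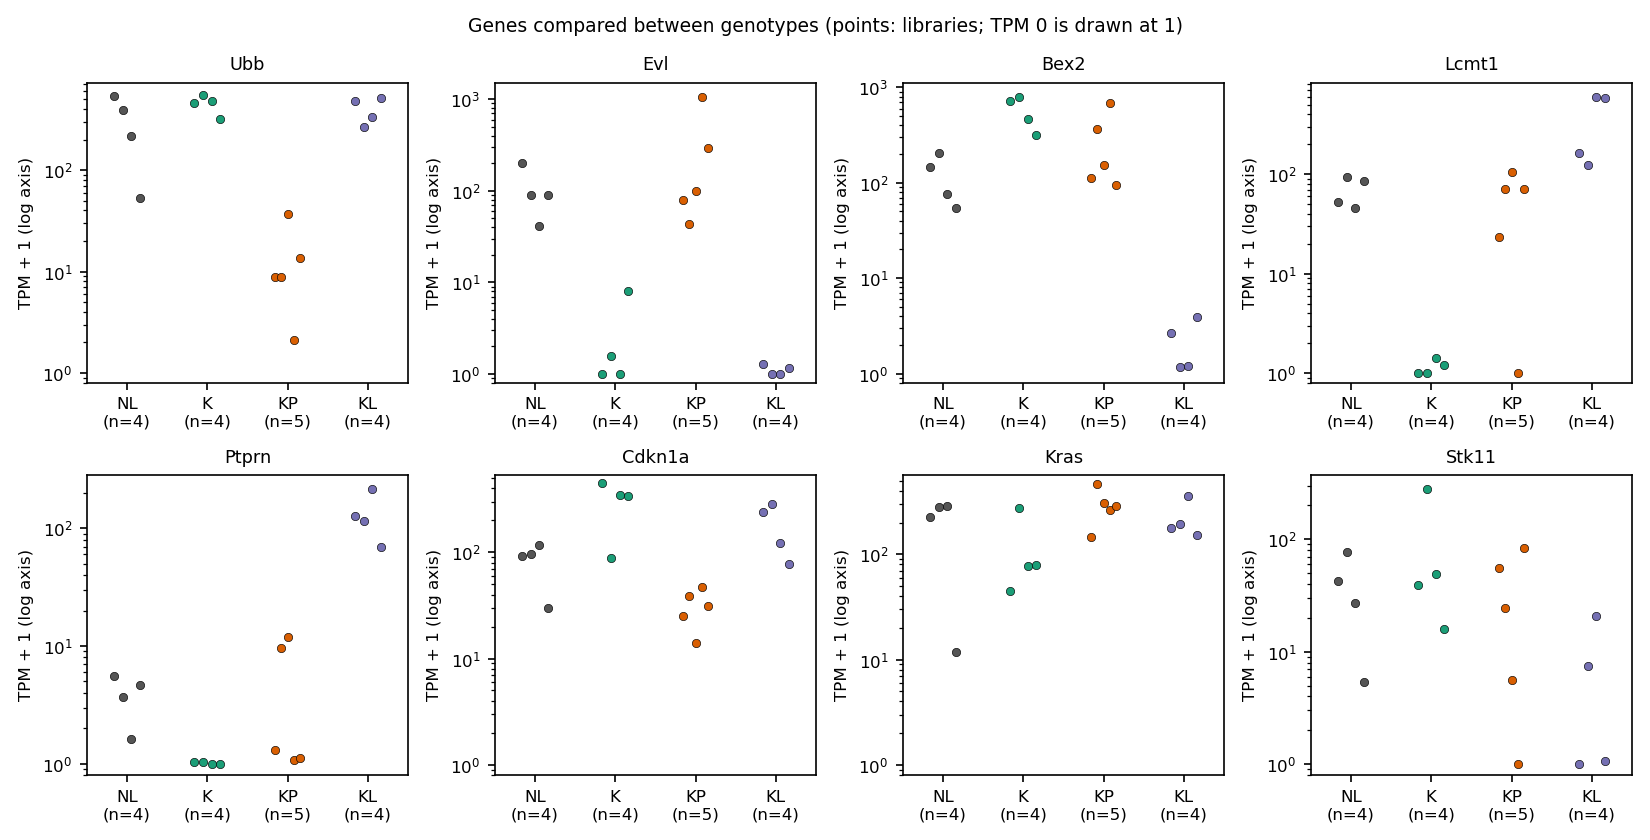
TPM + 1 on a log axis for Ubb, Evl, Bex2, Lcmt1, Ptprn, Cdkn1a, Kras and Stk11 in each library of the 4 groups, with values of 0 drawn at 1. Each point is a library; Ubb averaged 13.1 TPM in KP and 451.5 in K, and Bex2 1.22 TPM in KL and 577 in K.

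KL against K asks what LKB1 loss adds. The X-linked gene Bex2 (ENSMUSG00000042750, X:136066564-136068236) fell from 577 ± 223 TPM in K (SD, n = 4) to 1.22 ± 1.3 in KL (n = 4), a log2 change of -8.13 ± 0.85 (adjusted p = 2.63e-05), and was at 120 ± 69.6 TPM in NL. Its neighbour Bex4 was listed at 0 in all 4 KL libraries and at 66.18 to 432.22 TPM in K (-7.01, adjusted p = 0.368, not passing). Lcmt1 (ENSMUSG00000030763, 7:123369784-123430358), which methylates the phosphatase PP2A, rose from 0 to 0.41 TPM in K to 121.69 to 598.12 in KL (7.99 ± 1.19, adjusted p = 0.00508), and was at 44.29 to 93.55 in NL, so K was the group near 0. Ptprn (ENSMUSG00000026204, 1:75247027-75264502) was at 0 to 0.04 TPM in K, 131 ± 61.5 in KL and 0.63 to 4.61 in NL (6.90 ± 1.06, adjusted p = 0.00535). NRF2 target genes, which answer oxidative stress, had 12 of 15 negative changes, with Gstm1 at -4.24 ± 1.14 (adjusted p = 0.673), and a relative mean of -1.16 (adjusted p = 0.0268, and 0.681 with an estimated correlation). Ribosomal protein genes had 28 of 31 negative at a relative mean of -0.45 (adjusted p = 0.0215, and 0.658 with an estimated correlation). The lists on LKB1 were not called: genes high in LKB1-deficient human lung adenocarcinoma (adjusted p = 0.422) and CREB-CRTC targets (0.542), with Sik1, a member of both, at 2.72 ± 1.08 (adjusted p = 0.939). The type I interferon-stimulated list had a relative mean of 0.03 and was not called (adjusted p = 0.986).

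These were the only 3 genes called in KL against K (2 higher, 1 lower, 635 at an unadjusted p under 0.05), and 2 of 41 lists were called, 0 of them by fry. Bex2 was called in all 24 alternatives run for it. Leaving out K2, KL3 and KL4, chosen after seeing the data, ended the calls of Lcmt1 (adjusted p = 0.416, range over its alternatives 0.000472 to 0.416) and Ptprn (0.142, range 0.00133 to 0.146). The NRF2 list was not called without K3 (-1.06, adjusted p = 0.0941), K4 (-0.98, 0.117), KL3 (-1.03, 0.0618) or KL4 (-0.76, 0.163). The ribosomal list was not called without K2 (-0.39, 0.119), K3 (-0.38, 0.0842), KL1 (-0.32, 0.0844) or KL2 (-0.30, 0.0879).

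KL against KP sets the 2 tumour suppressors against each other. Bex2 was lower in KL (1.22 ± 1.3 TPM, SD, n = 4) than in KP (282 ± 249, n = 5), a log2 change of -6.76 ± 0.81 (adjusted p = 0.000271). Evl was at 0 to 0.28 TPM in KL and 42.32 to 1060.82 in KP (-7.18 ± 1.04, adjusted p = 0.00315), and Ubb at 397.5 ± 118.5 TPM in KL and 13.1 ± 13.5 in KP (5.32 ± 0.83, 0.00663). Ptprn (5.43 ± 1.01, adjusted p = 0.056) and Cdkn1a (2.47 ± 0.77, 0.961) did not pass. Limma called 3 genes (1 higher, 2 lower, 536 at an unadjusted p under 0.05), and camera called 0 of 41 lists, as did fry. The interferon-stimulated list had a relative mean of -0.52 and the interferon-gamma list -0.84 (adjusted p = 0.181 for each). The latter was called without KL2 (-1.22, adjusted p = 0.0175) and with no filter (-0.72, 0.0454). A fit of only these groups called 0 genes, with adjusted p of 0.115 for Bex2 (range over its alternatives 2.76e-05 to 0.115), 0.115 for Evl (0.000989 to 0.141) and 0.325 for Ubb (0.00188 to 0.438). The call of Ubb also ended without KL1 (5.21, adjusted p = 0.0583), and the count was 5 without KP4 or KP5.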

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

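The splits of the libraries and the tests with the genes above 0, the cell markers, the column numbers, the paralogs and the chromosome segment were chosen after the results were seen; the test of the interferon-stimulated list with vessel and immune cell scores was written before its result was seen.

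Most genes that changed between adenomas and adjacent normal lung were lower, 536 of 548, and genes of blood, vessels and alveolar type 1 cells were among them. None of the other 99 splits of the 100 drawn gave as many genes (1 of 100 with the real one, highest other 22), which argues against chance between libraries for the count. The splits exchanged libraries, and the labels tie no region to an animal, so chance between animals was not tested by any of them. The same held for K (1 of 35 splits, 238 against 1), KP (1 of 100, 182 against 43, the latter with KP1 on the side of NL) and KL against NL (1 of 35, 163 against 5). With 35 splits, 1 of 35 is the smallest share that can be reached. With the number of genes above 0 as a covariate 89.8% of the 108 genes called were lower (86.7% to 93.1% with each library left out; 102 of the 108 were among the 548), against fewer genes above 0 as the whole cause, though the median change of all genes went from -0.78 to 0.01 with it and among genes above 0 in every library the split was only 9 higher and 25 lower, and 8 and 9 in KL. More blood, vessel and alveolar type 1 cells in the normal regions cannot be told apart from lower expression within the same cells: 97.5% of the 40 members of those 3 lists were lower, against 77.1% of all genes, which restates the pattern and does not favour either. The genotype itself and the scaling, which changed the split of calls to 35 higher and 112 lower under quantile normalization, stay open.

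A few genes set a genotype group far apart from another, with values near 0 for Ubb in KP (-5.53 against K, 5.32 for KL against KP), Bex2 in KL (-8.13 against K, -6.76 against KP), Evl in K and KL (6.42 for KP against K, -7.18 for KL against KP), and Lcmt1 in K (7.99 for KL against K), and Ptprn was higher in KL than in K (6.90). For the number of genes chance could not be excluded: 11 of 100 splits gave at least 2 genes in KP against K (highest other 20), 2 of 35 at least 3 in KL against K (highest other 4) and 9 of 100 at least 3 in KL against KP (highest other 43), and the splits with 20 and 43 could reflect a structure of the samples, which was not tested. A batch of the libraries numbered 28 to 30 is argued against for Ubb near 0 in KP, since 0 of them are KP. With a term for them every change was at least 5.4 times its error and 7 of 8 calls held. The call of Ubb in KL against KP ended (5.32 ± 0.83 before, 5.18 ± 0.96 after, limma adjusted p = 0.0955), because its error rose. These 8 changes were picked as called in the same libraries, so a large ratio to the error was likely beforehand. With those 3 libraries left out only 2 of the 8 calls held, both of Bex2. Every change was then at least 4.5 times its error, with adjusted p of 0.0501 to 0.416 for the others. Evl was then at 6.33 ± 1.11 in KP against K and -7.15 ± 1.27 in KL against KP. In KL against K, Lcmt1 was at 6.89 ± 1.55 and Ptprn at 6.91 ± 1.3. As the whole cause, such a batch is thus argued against for Bex2, Evl, Lcmt1 and Ptprn too. A part in the size of a change is not excluded, as for Lcmt1, at 7.99 before. Reads passing to a paralog cannot be told apart from lower expression: as TPM times exon length, Ubc gained 12.8% of what Ubb lost (88.1% with 2 errors added) and the relatives of Bex2 gained -27.7% of what it lost, a further loss (74.1%, or 75.4% with the widest transcript lengths), and errors this wide do not decide. A chromosome segment carried along with the Trp53 allele cannot be told apart from p53 loss for Ubb, which lies 7 Mb from Trp53. Within 10 Mb of Trp53, 5 of 240 genes, Ubb itself among the 5, had an unadjusted limma p under 0.01, 2.08% against 0.88% elsewhere (one-sided Fisher exact p = 0.0652). Within 1 Mb of Ubb, 0 of 18 genes had one (smallest limma p 0.0911). These genes are too few to decide, and the share near Trp53 counts Ubb toward its own explanation. Within 1 Mb of Bex2, 3 of 13 genes had an unadjusted limma p under 0.05 in KL against K, the smallest 0.00015 for Bex4. Of all 12239 genes 635 had one. The numbers were 0 of 5 near Lcmt1 and 2 of 27 near Ptprn in KL against K, and 0 of 9 near Evl in KP against K. A change of the region around Bex2 was not tested further and stays open. Animals shared within a group and the genotype stay open for all 5 genes set apart between genotypes.

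The interferon-stimulated list stood lower in the adenomas, with a mean relative to other genes of -1.02 ± 0.25, a call of camera with its preset correlation that ended with an estimated one (adjusted p = 0.155 in all adenomas, 0.235 in K, 0.404 in KP and 0.186 in KL). For the list, no other split gave as small a camera p in all adenomas (1 of 100 splits, camera p 5.39e-05, best other 0.000115), in K (1 of 35, 0.000131 and 0.000154) or in KL (1 of 35, 5.64e-05 and 0.000554). This argues against chance between libraries there, but only weakly in K and in all adenomas, where the best other p was close. Chance between animals was not tested. With 35 splits, 1 of 35 is the smallest share that can be reached. In KP 27 of 100 splits gave as small a p (0.0117, best other 0.000547), so chance stays open there. Fewer genes above 0 in the adenoma libraries are argued against as the whole cause, since with that covariate the value was -1.11 ± 0.32 (adjusted p = 0.000379), though with only genes above 0 in every library, 5 of the list, no comparison with NL was called (-0.749 ± 0.53, adjusted p = 0.3, in all adenomas and -0.332, 0.823, in K). Fewer vessel and immune cells in the adenoma regions cannot be told apart from a lower response within the tumour cells: with the mean score of those lists (59 genes) as a covariate the value was -1.23 ± 0.63 (adjusted p = 0.0553), the call ending because the error rose. KRAS and the genotypes stay open as biological differences.

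Differences between the genotype groups were also found in list means. For KP against K these were interferon-gamma-inducible genes (mean log2 change 1.51; 4 of 100 splits gave as small a camera p as 4.01e-06, best other 7.48e-07), T cells (1.30; 3 of 100, 0.000518 and 0.000157) and glycolysis and hypoxia genes (-0.91; 18 of 100, 0.00195 and 1.64e-05). For KL against K they were NRF2 target genes (-1.19; 3 of 35, 0.00131 and 0.00021) and ribosomal protein genes (-0.48; 3 of 35, 0.000524 and 0.000135). These lists were picked by their p from 41, and over all 41 the smallest p was as small in 20 of 100 splits for KP against K and 22 of 35 for KL against K, so chance was not excluded for any. None was called with an estimated correlation (adjusted p = 0.771, 0.771 and 0.885 in KP against K, 0.681 and 0.658 in KL against K), and the T cell list was not called without K3, K4 or KP2.

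Single libraries stood apart from the rest of their group in 43 of 352 values tested. The limit used passes about 1 in 20 values only under a normal distribution, and many of these values have a floor at 0. How many of the 43 chance would give is therefore unknown. The ratio given is the gap to the nearest library over the whole range of the group. Where all other libraries are at 0 it is 1 whatever the value, as for S100a8 in K. KP1 stood apart in the globin share (0.819; 1.2% against 0.15% to 0.34%), the surfactant share (0.795), Alas2 (0.746) and Usp18 (1). KP2 did so in Hpgd (0.835) and Sik1 (0.98). KP4 stood apart in the lists of lung lineage transcription factors (0.73), genes high in LKB1-deficient adenocarcinoma (0.942), glycolysis and hypoxia (0.903), NRF2 targets (0.766) and ribosomal proteins (0.737), and in Bex4 (0.865). KL1 stood apart in Mt2 (0.96), Tmem100 (0.941), Alas2 (0.959), Clec14a (0.884), Ifit3b (1) and Usp18 (1), and KL2 in the 1 measured cardiac muscle gene (1), Ifit3 (0.95) and Cxcl9 (0.957). KL4 did so in the surfactant share (0.849), the list of interferons, receptors and kinases (0.923) and Rpl3 (0.917). K2 stood apart in the lists of alveolar type 2 cells (0.913), proliferation (0.966) and gastric and gut lineage (0.91), and in Mfap4 (0.91), Igfbp2 (0.914) and Ifit3 (0.851). K3 did so in Alas2 (1), Dpep1 (0.833) and S100a8 (1), and K4 in the mesothelial list (0.945), Trp53 (1), Ifit3b (0.933) and Sik1 (0.93). Among NL libraries these were NL1 for Trp53 (0.869), NL3 for proliferation (0.86) and Mfap4 (0.939), and NL4 for cardiac muscle (0.846), Kras (0.921) and Dpep1 (0.851).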

How the results depend on the processing

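The settings restricted to genes above 0 in all 17 libraries, to adenoma libraries with at least 10000 genes above 0, or without (or with a term for) the libraries numbered 28 to 30 were chosen after the results were seen; the rest were set before. Because the depth is unknown, it cannot be said which values of 0 more reads would have filled. Lists called at the start kept call and direction in 2053 of 2371 values, lost the call in 303 and turned in 15, and lists not called gained a call in 19 of 739. Genes called kept call and direction in 3401 of 4701 values and lost the call in 1300, and genes not called gained it in 265 of 9255. Of 181 gene changes called at the start, 32 were called in every alternative run for them and 48 in under 50%. The cause was not tested for any change listed here, except that settings with fewer libraries or genes also change what can pass.

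Genes changed in all adenomas, K, KP and KL against NL were 548, 238, 182 and 163. They were 323, 151, 76 and 85 with a pseudocount of 0.1, and 213, 109, 70 and 57 at a mean TPM of 5 or more, which tests fewer genes. Quantile normalization gave 147, 68, 53 and 59, library quality weights 1378, 625, 449 and 471, and the covariate for genes above 0 gave 108, 33, 59 and 24. With only genes above 0 in every library, 2558 in all, they were 34 (9 higher, 25 lower), 15 (3 and 12), 24 (7 and 17) and 17 (8 and 9). Median-ratio scaling gave 136 for K and 118 for KP. Fits of only the groups compared gave 41 for KP and 84 for KL, and the replicate block 53 for KP. Without the libraries numbered 28 to 30 the counts were 300 for all adenomas, 137 for K and 6 for KL, and with a term for them 315 for all adenomas and 21 for KL. Without adenoma libraries under 10000 genes they were 357 for all adenomas, 49 for KP and 27 for KL. Leaving out 1 library gave 224 to 599 for all adenomas, 85 to 209 for K, 61 to 155 for KP and 47 to 164 for KL.

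Between genotypes the counts were 2 for KP against K, 3 for KL against K and 3 for KL against KP. For KP against K limma gave 1 with a pseudocount of 0.1, 4 with quality weights, 1 with genes above 0 in every library, 15 without adenoma libraries under 10000 genes (all higher, 0 shared with the 2 genes), and 0 without the libraries numbered 28 to 30 or in a fit of only these groups, against 604 at an unadjusted p under 0.05 in the full fit. For KL against K it gave 1 with genes above 0 in every library and 1 without the libraries numbered 28 to 30. For KL against KP it gave 5 with quantile normalization, 5 with quality weights, 1 without adenoma libraries under 10000 genes, 1 without the libraries numbered 28 to 30, and 0 in a fit of only these groups (536 at an unadjusted p under 0.05 in the full fit). Leaving out 1 library gave 0 to 4, 3 to 4 and 2 to 5.

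The type I interferon-stimulated list, as its mean relative to other genes, was -1.02 in all adenomas, -1.22 in K, -0.67 in KP and -1.19 in KL against NL. With an estimated correlation the adjusted p was 0.155, 0.235, 0.404 and 0.186, and none was called. With genes above 0 in every library the values were -0.749, -0.332, -1.23 and -0.688, none called, and -0.896 for KP against K, -0.357 for KL against K and 0.54 for KL against KP. A pseudocount of 0.1 gave -0.707 for KP against NL, not called, 1.04 for KP against K and -1 for KL against KP. Median-ratio scaling gave -0.587 for KP against NL, not called, and leaving out adenoma libraries under 10000 genes 0.369 for KL against K. Leaving out 1 library gave -1.13 to -0.807 in all adenomas, -1.36 to -1 in K, -0.804 to -0.42 in KP and -1.29 to -0.968 in KL against NL, 0.414 to 0.799 for KP against K, -0.0996 to 0.187 for KL against K and -0.766 to -0.363 for KL against KP.

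The p53 target list, not called for KP against K, was called in 6 of 27 alternatives (adjusted p from 0.00742 to 0.913), and likewise in 5 of 26 for K against NL and 1 of 27 for KL against KP. Other lists not called at the start gained a call in few alternatives: interferon-gamma-inducible genes in 2 of 27 for KL against KP and 1 of 26 for KL against K, genes high in LKB1-deficient adenocarcinoma in 1 of 34 for all adenomas and 2 of 26 for KL against NL, and the type I interferon-stimulated list in 1 of 27 for KP against K.

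The direction of camera turned for 11 results of called lists with genes above 0 in every library, where lists keep few members. Camera takes its direction from the members' test statistics and not from their mean, so it could turn upward while the relative mean stayed negative, as for B and plasma cells in all adenomas, K and KL. The relative means there were -0.242, -0.74, 0.403 and -0.39 for B and plasma cells in all adenomas, K, KP and KL against NL, 0.0948 for complement in KP, 1.59, 2.65 and 1.75 for neutrophils in all adenomas, K and KP, and 0.589, 0.542 and 1.05 for smooth muscle and pericytes in all adenomas, KP and KL. Quantile normalization turned ribosomal proteins in KL against NL to -0.173. Fry, which asks whether members fall or rise and not whether they differ from other genes, turned NRF2 targets in all adenomas (adjusted p = 0.97), RAS-MAPK output in KP (0.965) and ribosomal proteins in KL (0.804).

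The replicate numbers gave no sign of pairing: after group means were removed, 24 pairs of libraries with the same number had a mean correlation of 0.001 (range -0.051 to 0.071), and 3 of 17 libraries correlated best with their own number. With the number as a block 412, 183, 53 and 136 genes changed in all adenomas, K, KP and KL against NL.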

Other observations

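The reading of Xist and the Y-linked genes was chosen after the values were seen; the gene and list tests were set beforehand, as were the alternatives counted here apart from those with genes above 0 in every library, without adenoma libraries under 10000 genes, and without or with a term for the libraries numbered 28 to 30.

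Several lists that the comparisons above left out were measured in all adenomas against NL. Genes of mesenchymal transition and invasion had 1 of 9 members lower, the transcription factor Snai2 (-3.23 ± 0.60, adjusted p = 0.00281), and a relative mean of -0.74 (camera adjusted p = 0.0232, and adjusted p = 0.253 with an estimated correlation; not called without NL1, 0.0564, or NL4, 0.0528). Dendritic cell genes had 2 of 7 lower, Ccr7 (-2.46 ± 0.53) and Clec9a (-2.88 ± 0.80, called in 9 of 31 alternatives, adjusted p up to 0.519), without a call of the list (0.166). Sterol and fatty acid synthesis had 1 of 22 lower, the squalene epoxidase Sqle (-2.89 ± 0.62, adjusted p = 0.00973), and was not called (0.776). Immediate early and heat shock genes had 1 of 17 lower, Klf4 (-3.42 ± 0.98, called in 10 of 32 alternatives, adjusted p up to 0.254), and were not called (0.832). Mesothelial genes had 1 of 2 lower, Gpm6a (-3.17 ± 0.82; list adjusted p = 0.166), and club and secretory genes 1 of 6, Aldh1a1 (-3.99 ± 1.04; 0.345). CREB-CRTC targets had 1 of 12 lower (Pde4b, -3.40 ± 0.85; list adjusted p = 0.623) and glycolysis and hypoxia 1 of 21 (Ankrd37, -4.01 ± 1.00; 0.141). Of the other genes named here, Snai2 was called in 28 of 30 alternatives, Ccr7 and Sqle in 26 of 30, Gpm6a in 22 of 31, Aldh1a1 in 20 of 31, Pde4b in 25 of 32 and Ankrd37 in 23 of 31. No member was called by limma in the lists of p53 targets (25 genes, list adjusted p = 0.317), genes high in LKB1-deficient adenocarcinoma (9, 0.166), integrated stress and unfolded protein response (16, 0.208), gastric and gut lineage (2, 0.149) and cardiac muscle (1, 0.317).

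Some list calls differ in sign between mean, median and test. Other genes had a mean change of -0.85 in all adenomas against NL. Ribosomal protein genes had a mean of 0.14 with 0 of 31 called, and camera placed them higher (adjusted p = 1.83e-06, and 0.0355 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.717, range over its alternatives 1.5e-10 to 0.717). Mitochondrially encoded genes had a mean of -0.86 and a median of 0.31, with mt-Nd3 the 1 of 12 that fell (called in 16 of 31 alternatives, adjusted p up to 0.572), and were placed higher (adjusted p = 0.00308, and 0.155 with an estimated correlation). NRF2 targets had a mean of -0.04 and a median of 0.27 and were placed higher (adjusted p = 0.0232, and 0.397 with an estimated correlation; not called without KL1, 0.0751, or NL4, 0.0815). RAS-MAPK output genes in KP against NL had a mean of -0.06 and a median of 0.23 and were placed higher (adjusted p = 0.0437, and 0.382 with an estimated correlation), and keratin-high genes in K against NL a mean of 0.33 and a median of -0.19 (adjusted p = 0.0121, and 0.33 with an estimated correlation).

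The female-specific transcript Xist and the summed Y-linked genes differed between libraries within groups, and the groups were not balanced in them. Xist was at 14.59 TPM in K1 and 11.22 in K2 and under 1 in K3 and K4, at 19.97 to 95.25 in KP1 to KP4 and 0 in KP5, and at 56.67 in NL4 against 1.21 to 1.67 in NL1 to NL3. The Y-linked sum was 0.05 TPM in K1 and K2, 35.63 in K3 and 6.77 in K4. It was 0 to 0.45 in KP1 to KP4, 143.62 in KP5, 314.31 in KL3, 50.14 in KL1, 42.91 to 46.17 in NL1 to NL3 and 0 in NL4. No comparison was adjusted for sex, so some changes could follow it, above all in KP against NL and KL against KP. This was not tested. KL2 held both (7.17 and 37.99 TPM) and KL4 neither (0.02 and 0). In KP, Ubb was at 1.1 to 36.07 TPM in libraries of both kinds.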
